A study of Homo sapiens with 5 samples.

How the data were processed

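BRG1 binding was profiled by CUT&RUN, in which an antibody-directed nuclease releases DNA fragments around a chromatin protein, in MCF7 cells, an oestrogen receptor-positive human breast cancer line. Cells received 500 nM abemaciclib, an inhibitor of CDK4 and CDK6, or the solvent DMSO for 2 days. There were 2 BRG1 libraries per treatment and 1 library made with non-specific IgG from DMSO cells. Yeast DNA was added as a spike-in, per the labels. Nothing in the labels says that the replicates came from separate cultures, so a p-value may measure technical spread only.

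The deposited files were 5 peak lists, one per library, with no pooling of replicates. The submitters' processing notes name Bowtie2 2.3.4.1, deepTools 3.5.0 and MACS2 2.2.7.1 and the builds hg38 and sacCer3. The control library, filters and settings of the peak calling are not given in the sources used here. Each deposited list gives a score, a fold ratio at the summit, and the −log10 p-value and −log10 q-value of each peak, as the authors' peak caller wrote them. These values are the authors' and were used to rank, describe or filter peaks inside their own list, and, as set out next, to recover pileups that describe depth. The smallest −log10 q was 1.32, 1.31, 1.30 and 1.32 in the BRG1 lists and 1.32 in the IgG list. Spike-in factors and read counts were not used here, so no level of binding was compared between libraries, and a region that was not called may still have been bound.

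Read depth is unknown. As a description of it, the fragment pileup at each summit and its background were recovered from the deposited fold and −log10 p-value, taking the fold as the ratio of pileup plus 1 to background plus 1. Whole-number pileups were accepted when the −log10 p-value matched within 0.002 plus 5e-05 of its value. This step was chosen after the data were seen. Between 98.8% and 100% of the peaks of a library gave a whole pileup. In simulated peaks, 99.98% of 15331 pileups were recovered at the lower background and 100% of 16367 at the higher one.

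Peaks on chromosomes 1 to 22 and X were used. The 4 BRG1 lists were merged into consensus regions wherever peaks overlapped by at least 1 bp. A region was only DMSO if called in both DMSO libraries and neither abemaciclib library, and only abemaciclib in the opposite case. Regions called in exactly 1 DMSO and 1 abemaciclib library, named crossed pairs, served as the reference. They were called in as many libraries, and a full gain or loss with treatment cannot produce them where detection is complete. A partial change with incomplete detection can, so they are not free of treatment effects. The 4 libraries split into pairs in 3 ways, of which 1 follows the treatment. Library-level values were compared by a 2-sided exact permutation test of the 6 assignments, whose smallest possible p is 0.333. Classes of regions were compared by 2-sided Fisher's exact tests. Regions are not replicates, so those p-values describe these libraries. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only. Percentile ranks run from 0 to 100 within a list by −log10 q.

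Gene positions came from a RefSeq table of assembly GRCh38.p14, the assembly family of hg38, with 19974 protein-coding genes used. The table gives no strand, so a transcription start could not be told from a gene's other end. A summit within 1 kb of either end of a protein-coding gene, here called a gene end, replaced the promoter that was planned. Regions were assigned to the gene with the nearest end within 50 kb, which gave 26629 of 35229 regions a gene. Before the data were examined, 13 gene lists with 391 genes were fixed, all of which matched the table: E2F targets and cell cycle, oestrogen response and luminal, AP-1 and immediate early, interferon and antigen presentation, p53 response and senescence, basal and mesenchymal, YAP/TEAD targets, apoptosis regulators, lysosome and autophagy, SWI/SNF subunits, housekeeping, leukocyte markers, and neuronal and liver markers. Each list was tested in only-DMSO and only-abemaciclib regions against crossed pairs, with Benjamini-Hochberg adjustment over 26 tests and a threshold of 0.05.

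Named regions followed a rule fixed in advance. It took the 10 only-DMSO and 10 only-abemaciclib regions with the highest smaller percentile rank, and up to 3 of each class per list. It also took the 5 regions called in all 4 libraries with the highest smallest percentile rank, and 28 chosen loci. The planned motif tests were not run because no genome sequence was at hand. Alternatives were a stricter threshold (−log10 q of at least 5), equal list lengths, other overlap rules, removal of regions with IgG peaks, all contigs, peaks above the median of both lists, other gene-end definitions, other assignments and backgrounds for the lists, leaving out each library, and same-numbered libraries as pairs. Added after the data were seen were the direct comparison of only-DMSO with only-abemaciclib regions for the lists, assignment by gene body, and removal of 1-Mb windows that hold an IgG peak. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The merging and list tests were checked on simulated data. The counts of 1887 only-DMSO and 1953 only-abemaciclib regions were matched to 100%. That was fixed in advance, because simulated peaks of a site always overlapped and sites lay far apart. It checks the code only and does not cover crowded or chained peaks. A list with a true odds ratio of 3 passed an unadjusted 0.05 in 79.5% of 1000 draws, against 3.0% with a ratio of 1. These list rates are for unadjusted tests. The simulated list was also commoner in crossed pairs than any list tested here. The simulated class was larger than the 1028 assigned only-abemaciclib regions. The rates therefore do not give the power of the tests that were run, adjusted or not.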

Results

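BRG1, the ATPase encoded by SMARCA4 that drives SWI/SNF chromatin remodelling, was mapped in MCF7 cells kept for 2 days in DMSO or 500 nM abemaciclib. The series was made to benchmark normalisation methods for differential binding, and the comparison it holds is abemaciclib against DMSO, with 2 libraries each and 1 IgG library as background. On chromosomes 1 to 22 and X, 19228 and 22957 BRG1 peaks were listed with DMSO and 21619 and 21993 with abemaciclib. The IgG list held 118. The median summit pileup recovered from the lists was 15 and 16 fragments with DMSO and 11 and 13 with abemaciclib, over commonest backgrounds of 0.869, 0.873, 0.592 and 0.814 fragments per base. The pileup, which depends on sequencing depth as well as on binding, was lower in both abemaciclib libraries than in either DMSO library.

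The highest-ranked regions called in all 4 libraries lay on chromosomes 20 and 17, which also held 35 and 28 of the 118 IgG peaks. Rank by −log10 q is not a level of binding, and DNA copy number was not measured here. The 5 top regions called in all 4 libraries included 2 next to PARD6B, a cell polarity gene (chromosome 20, 50730353 to 50732650, 0.338 kb from a gene end, and 50761104 to 50763243, 7.997 kb away). The others lay 19.8 kb from CYP24A1, which encodes the vitamin D 24-hydroxylase (chromosome 20, 54122837 to 54124417), inside BCAS3 (chromosome 17, 61356096 to 61357271) and 21.5 kb from NACA2 (chromosome 17, 61567987 to 61569840). Of 35229 consensus regions, 11292 (32.1%) were called in all 4 libraries and 13292 in 1 library. The number of peaks averaged 21092.5 ± 2637 (SD, n = 2) with DMSO and 21806 ± 264 (SD, n = 2) with abemaciclib, a difference of 713.5 that was within the spread of the DMSO libraries (exact permutation p = 1). The difference turned to −2698.5 at −log10 q of at least 5, and to −1151 without the first DMSO library. Abemaciclib peaks were narrower, with median widths of 388 and 426 bp against 513 and 538 bp, and covered 10.7 ± 0.640 Mb (SD, n = 2) against 13.1 ± 2.10 Mb (SD, n = 2). For both measures the groups did not overlap, and the exact permutation p of 0.333 is the smallest that n = 2 allows.

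Libraries of the same treatment shared more regions than libraries of different treatments on average, mostly through the DMSO pair. The regions called in both libraries made up 0.624 of those called in either for the DMSO pair and 0.523 for the abemaciclib pair. The 4 pairs across treatments gave 0.495, 0.527, 0.493 and 0.533, so 2 of them exceeded the abemaciclib pair. By base pairs, the shared part was 0.561 for the DMSO pair, 0.464 for the abemaciclib pair and 0.434, 0.471, 0.417 and 0.459 across treatments, of which 1 exceeded the abemaciclib pair.

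Of the loci fixed in advance, which included the luminal programme, the cell cycle and AP-1 genes, most had the same gene-end calls in the 2 treatments. A peak lay at a gene end in all 4 libraries for 15 of the 28 loci, including SMARCA4 itself, the oestrogen-responsive GREB1 and TFF1, the pioneer factor FOXA1, XBP1, CCND1, CDK4, E2F1, the proliferation marker MKI67, TOP2A, FOS, FOSL2, JUN, JUNB and IRF1. Another 7 had no gene-end peak in any library: ESR1, PGR, GATA3, CDK6, CCNE2, CDKN1A and ATF3. Only the outer ends of a gene were scored, so this does not mean that BRG1 was absent from these loci. Regions called in all 4 libraries were assigned to ESR1 (3), GATA3 (2), CDKN1A (2), ATF3 (2) and CDK6 (1), and none to PGR or CCNE2. RB1, which encodes the retinoblastoma protein phosphorylated by CDK4 and CDK6, had a gene-end peak in both DMSO libraries and neither abemaciclib library. MYC, MCM2 and STAT1 lacked one in the first abemaciclib library alone, and B2M and HLA-A had one in the second DMSO library alone. The IgG library had none at any of these loci. Away from or beside these gene ends, regions assigned to XBP1, FOXA1, MYC, RB1 and FOSL2 included an only-DMSO region. Those of ATF3 and IRF1 included an only-abemaciclib region, and those of FOS and JUNB 1 of each. At −log10 q of at least 5 the IRF1 region was not called in either abemaciclib library.

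Regions that followed the treatment were more frequent than regions that followed a mixed pair of libraries. Both DMSO libraries and neither abemaciclib library called 1825 regions, and both abemaciclib libraries and neither DMSO library called 1533. The 4 crossed pairs held 303, 389, 769 and 1030 regions. The treatment split therefore separated 3358 regions, against 1333 and 1158 for the crossed splits, 2.70 times their mean. With 3 splits no p under 0.333 can be reached. At −log10 q of at least 5 the balance shifted, to 2090 only-DMSO and 794 only-abemaciclib regions. Leaving out a library loosens the definition and raised the counts by over 1.5 times in most cases, to between 2062 (without the first DMSO library) and 5777 (without the second abemaciclib library) for only-abemaciclib regions and to between 2979 (without the first abemaciclib library) and 5475 (without the first DMSO library) for only-DMSO regions.

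**Figure D1:**
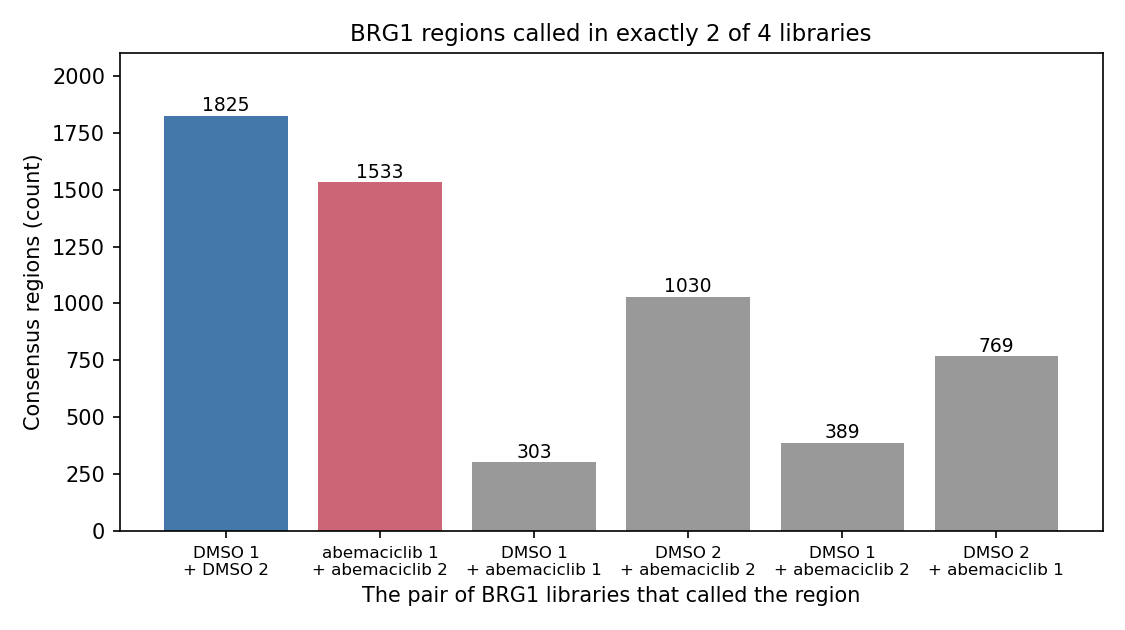
Number of consensus regions (vertical axis) called in exactly 2 of the 4 BRG1 libraries, for each pair of libraries (horizontal axis; numbers are replicates). The bars for 2 DMSO libraries (1825) and 2 abemaciclib libraries (1533) stand above the grey bars for 1 library of each treatment, which reach 1030.

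The only-abemaciclib regions of highest rank lay inside genes or between them, and none was within 1 kb of a gene end. Those inside genes were in SFXN5 (chromosome 2, 73038013 to 73038569), DGKH (chromosome 13, 42106043 to 42106414), GRIP2 (chromosome 3, 14587950 to 14588231), MAP3K9, a kinase of the JNK cascade (chromosome 14, 70754950 to 70755533), and MARCHF4 (chromosome 2, 216315785 to 216316367). Between genes, the nearest gene ends belonged to MAF, a bZIP transcription factor (158 kb; chromosome 16, 79758987 to 79759380), MTAP (118 kb), SLITRK3 (208 kb), KCNJ15 (57.9 kb) and DRAM2 (71.5 kb). In their weaker abemaciclib list these 10 regions stood between percentiles 84.4 and 90.7. The only-DMSO regions of highest rank stood between 75.2 and 81.2, and none of them was within 1 kb of a gene end either. They lay inside SCMH1, a Polycomb group gene (chromosome 1, 41240001 to 41240418), SPTLC2 (chromosome 14, 77581013 to 77581465), VTI1A (chromosome 10, 112741397 to 112742611) and TEX14 (chromosome 17, 58631197 to 58632209, with the nearest gene end that of IGBP1C), and near MSX2, a homeobox gene (25.3 kb), FIGN (233 kb), NDUFS4 (31.3 kb), SLC35A3 (3.98 kb), TOX3 (17.5 kb) and WNT7B, a WNT ligand (1.67 kb; chromosome 22, 45978713 to 45979295).

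Regions called only with abemaciclib lay farther from gene ends than the other classes. A gene end was within 1 kb for 11% of only-abemaciclib regions (95% interval 9.50 to 12.7), against 24.2% of crossed pairs (22.5 to 25.9), 23.8% of only-DMSO regions (21.9 to 25.9) and 42.1% of regions called in all 4 libraries. The share was 15.6% for regions called in 1 library. Regions of the first and second abemaciclib library alone had 14.3% and 12.95%. Those of the first and second DMSO library alone had 18.8% and 18.1%. A low share was thus not confined to regions called in both abemaciclib libraries, and every crossed pair holds a DMSO call. The odds ratio of only-abemaciclib regions against crossed pairs was 0.389 (0.324 to 0.468, Fisher's exact p = 4.13e-26), and that of only-DMSO regions was 0.982 (0.853 to 1.13, p = 0.829). The latter was 1.26 (Fisher's exact p = 0.00111) at −log10 q of at least 5, and 1.63 and 1.34 without the first and second abemaciclib library. The corresponding ratios between the pairs of the crossed splits were 1.40 (Fisher's exact p = 0.0259) and 0.636 (p = 0.00302), against 2.53 between only-DMSO and only-abemaciclib regions (p = 1.36e-22). Taken the other way round, as only-abemaciclib against only-DMSO, this last ratio was 0.396, and 0.549 and 0.698 without the first and second DMSO library, the latter no farther from 1 than the 0.636 of a crossed split. The ratio of only-abemaciclib regions to crossed pairs was 0.208 at −log10 q of at least 5. The median distance to a gene end was 23929 bp for only-abemaciclib regions, 14328 bp for only-DMSO regions and 13810 bp for crossed pairs. Over whole lists, 34.5% ± 1.63 (SD, n = 2) of DMSO peaks and 31.4% ± 0.433 (SD, n = 2) of abemaciclib peaks were near a gene end (exact permutation p = 0.333, the smallest possible), against 17.8% of IgG peaks (11.4 to 25.9). The difference of −3.12 percentage points between treatments was −1.96 without the first DMSO library and −4.27 without the second.

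**Figure D2:**
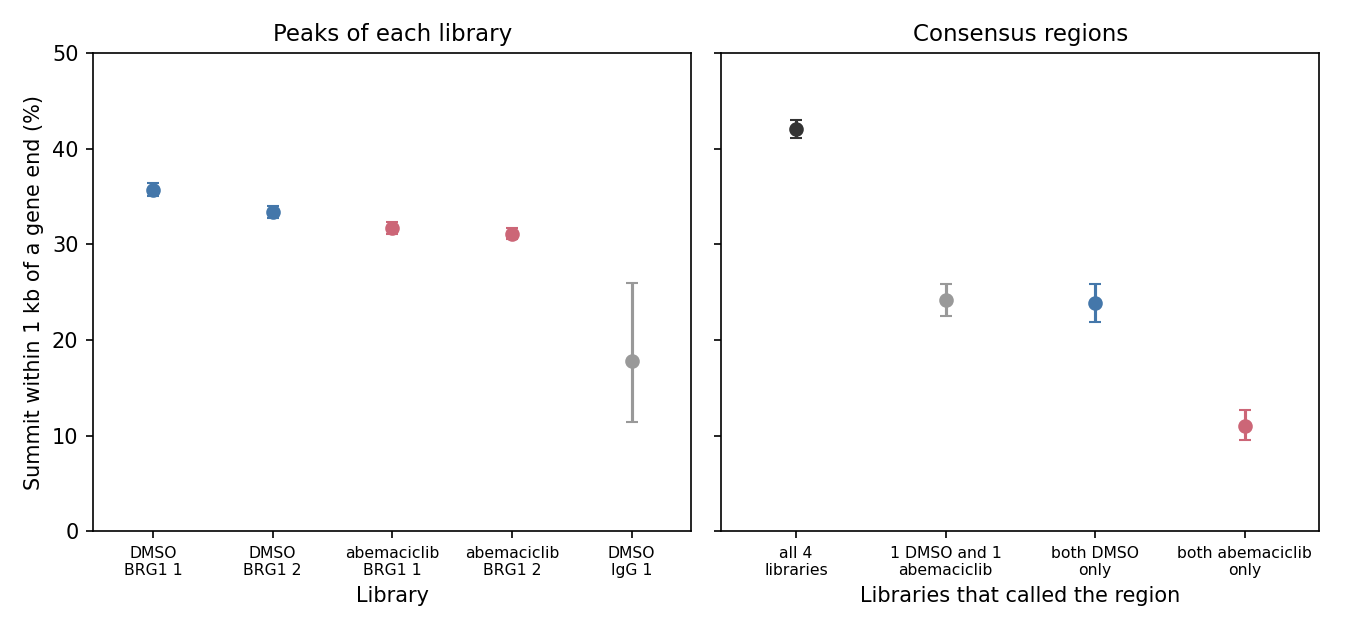
Percent of peak summits within 1 kb of the end of a protein-coding gene, for each library (left) and for consensus regions by the libraries that called them (right). Points are shares and bars exact 95% intervals; only-abemaciclib regions lie at 11%, below only-DMSO regions at 23.8% and regions called in all 4 libraries at 42.1%.

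At the level of genes, 5506 protein-coding genes had a peak at an end in all 4 libraries, 468 only in both DMSO libraries and 188 only in both abemaciclib libraries. Crossed pairs held 108, 86, 239 and 261 genes. In the E2F and cell cycle list, 25 of 65 genes were called in all 4 libraries. Its only-DMSO genes were CCNB1 and CCNB2, which encode mitotic cyclins, AURKB, KIF11 and RFC4, and its only-abemaciclib gene was BIRC5. A peak lay at an end of 44 and 51 of its genes with DMSO and of 35 and 37 with abemaciclib. Over all protein-coding genes these numbers were 7762 and 8600 against 7510 and 7532. For the 28 housekeeping genes they were 18 and 23 against 18 and 16, with RPLP0 and POLR2A called only with DMSO and 0 genes only with abemaciclib. Among 40 oestrogen response and luminal genes, the keratins KRT8 and KRT19, ELF3 and MLPH were called only with DMSO, and CA12 and NRIP1 only with abemaciclib. Gene calls rest on summits at gene ends: no only-abemaciclib region was assigned to NRIP1 and no only-DMSO region to POLR2A. The basal and mesenchymal list had CDH2, which encodes N-cadherin, CAV2 and LAMC2 only with abemaciclib, and 0 genes only with DMSO. These gene counts were not tested, and several calls were lost at −log10 q of at least 5. There the CCNB2, AURKB and CDH2 regions were called in 0 libraries, and the BIRC5, CA12 and CAV2 regions in 1 abemaciclib library. The BIRC5 region was also called in 1 library at equal list lengths.

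The lists were tested by the regions assigned to them, and none of the 26 Fisher's exact tests against crossed pairs passed after adjustment. Crossed pairs held at most 8 regions of any list, so a test that did not pass does not show that a list was unchanged. The smallest adjusted p was 0.825, and 1 test had an unadjusted p under 0.05. That test was the oestrogen response and luminal list in only-DMSO regions, with 15 of 1317 assigned regions against 8 of 1839 in crossed pairs (odds ratio 2.64, Fisher's exact p = 0.0317). Its 15 regions lay near 12 genes, among them SIAH2 (chromosome 3, 150756211 to 150757109), AGR3 (chromosome 7, 16905145 to 16905748), KRT8 (chromosome 12, 52949694 to 52950242, inside the neighbouring KRT18), FOXA1, XBP1, MYC, GRHL2 and CDH1. The only-abemaciclib regions held 1, at CA12 (chromosome 15, 63381824 to 63382119). The AP-1 and immediate early list held 6 only-DMSO regions, including those near DUSP1, FOSB and FOSL2, and 4 only-abemaciclib regions, including those near ATF3 (chromosome 1, 212561548 to 212561872), JUNB and FOS, against 3 in crossed pairs. At −log10 q of at least 5 the FOSL2, JUNB and FOS regions were no longer called in both libraries of their treatment. The E2F list held 6 and 3 regions, YAP/TEAD targets 7 and 0 (among the 7, CCN1, NT5E and LATS2), interferon and antigen presentation 2 and 1, p53 response 3 and 2, and basal and mesenchymal 1 and 3. Apoptosis regulators held 1 and 0, lysosome and autophagy 2 and 1, SWI/SNF subunits 2 and 1, and housekeeping genes 2 and 2. Leukocyte markers, for cells that this culture should lack, held 1 and 2, with a gene-end peak in all 4 libraries at 2 of 20 genes. Neuronal and liver markers held 1 and 0, with no gene-end peak in all 4 libraries at any of 20 genes.

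**Figure D3:**
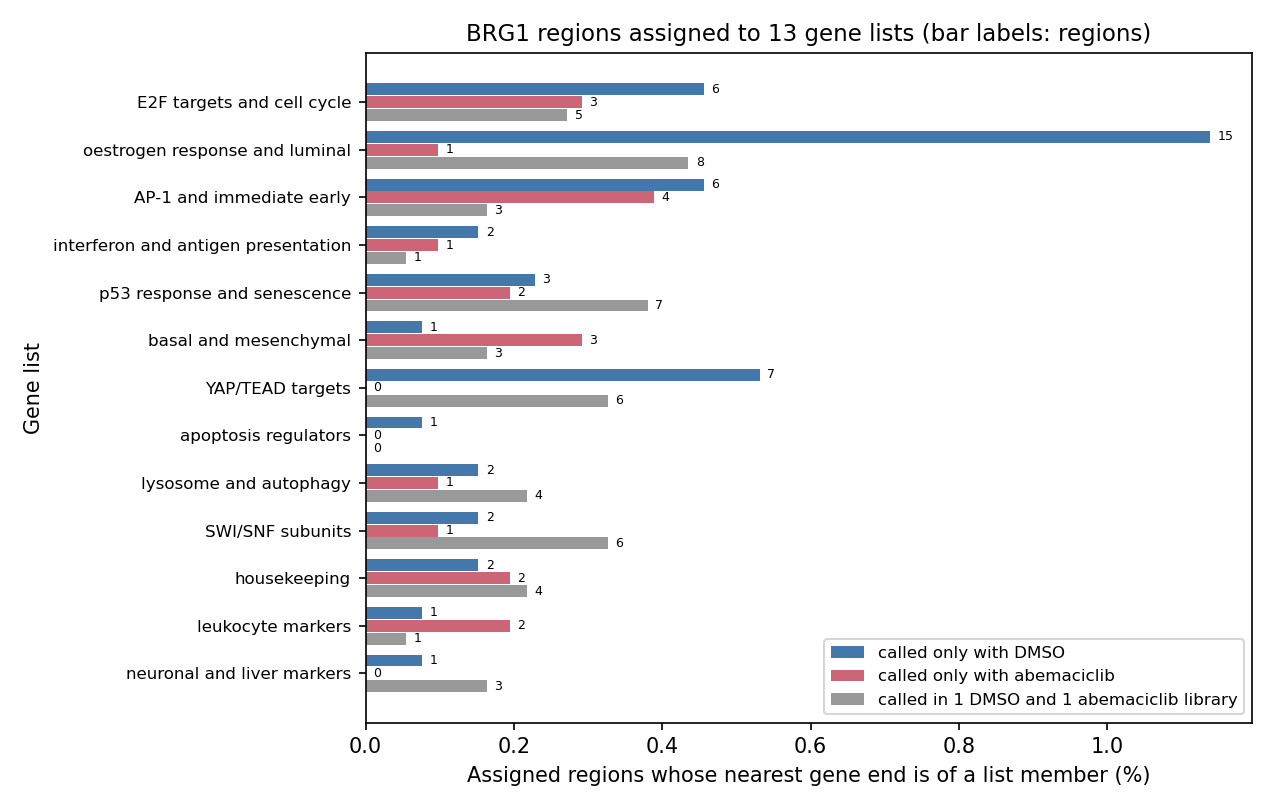
Percent of assigned regions whose nearest gene end belongs to a member of each of 13 gene lists (horizontal axis), for only-DMSO, only-abemaciclib and crossed-pair regions; numbers beside the bars are regions. The widest gap is for oestrogen response and luminal genes, with 15 only-DMSO, 1 only-abemaciclib and 8 crossed-pair regions.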

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

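The test of the share of only-abemaciclib regions in windows with IgG peaks was chosen after related results were seen, as was the use of those windows as an alternative.

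Peaks outside chromosomes 1 to 22 and X were left out of the comparisons except under the all-contigs alternative, and both abemaciclib libraries had more of them than both DMSO libraries. They numbered 150 and 175 with abemaciclib, a mean of 162.5, against 63 and 44 with DMSO, and the IgG library had 398 of its 516 peaks there. Decoy contigs held 72 and 89 of the abemaciclib peaks and 225 of the IgG peaks. Of the abemaciclib peaks, 58.8% overlapped an IgG peak (95% interval 53.2 to 64.2), and of the DMSO peaks 65.1% and 50% did, which is consistent with a background shared with the IgG library under both treatments. Whether abemaciclib raised that background was not tested, because there is 1 IgG library and it is from DMSO cells.

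The excess of regions that followed the treatment was weighed against list length, weak peaks and background. With every list shortened to 19228 peaks the treatment split was 3.18 times the mean crossed split, which argues against unequal list lengths. Most regions of both classes ranked low, with median smaller percentiles of 26.6 for only-abemaciclib and 22.8 for only-DMSO regions. Above the median of both lists stood 19.3% and 11.9%, against 2.97% of crossed pairs (odds ratios 7.82 and 4.43). That median was a −log10 q of 5.52 and 6.66 in the abemaciclib lists and 8.15 and 9.34 in the DMSO lists. The only-DMSO class was held to the higher medians, so the 11.9% were not weak within the DMSO lists. Every crossed pair was missed by a DMSO library, however, and no only-DMSO region was. The contrast thus cannot decide whether the weaker abemaciclib lists gave the class. The only-abemaciclib class was held to the lower medians, so its contrast with crossed pairs cannot decide whether weak peaks account for it. Windows of 1 Mb with an IgG peak held 8.09% of only-abemaciclib regions (6.77 to 9.57), too few for background there to give them all. They held 3.77% of crossed pairs (odds ratio 2.24, Fisher's exact p = 9.97e-09) and 3.62% of only-DMSO regions. For regions called in all 4, 3 and 1 libraries the shares were 5.09%, 4.27% and 5.00%. A part from background therefore stays open. The test counts regions as independent, although 10 of the only-abemaciclib regions in these windows form the BMP7 cluster described below. A uniform loss of signal with abemaciclib stays open for the only-DMSO regions, because 1.15% of them (0.714 to 1.75) ranked above the median shared region in both DMSO lists, between the bounds set for either outcome; preparation or depth that differed with treatment cannot be separated from the drug with 2 libraries each.

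The distance of only-abemaciclib regions from gene ends held after both corrections tried. Only-abemaciclib regions ranked higher than crossed pairs, with median smaller percentiles of 26.6 and 15.7. Ranks are within a list, however, and the median −log10 q was 5.52 and 6.66 in the abemaciclib lists against 8.15 and 9.34 in the DMSO lists. Equal ranks were thus not equal strengths, and rank cannot settle whether weaker peaks were the cause. Within deciles of rank the Mantel-Haenszel odds ratio against crossed pairs was 0.466 (0.386 to 0.563), and without windows that hold an IgG peak the odds ratio was 0.398 (0.330 to 0.482). Those windows held 124 of 1533 only-abemaciclib regions and 94 of 2491 crossed pairs, too few for their removal to bring the ratio near 1. Narrower and shallower peaks in the abemaciclib libraries remain an open technical difference. Regions called in 1 abemaciclib library alone also had low gene-end shares, 14.3% and 12.95%, and every crossed pair holds a DMSO call. The contrast with crossed pairs thus cannot tell a drug effect from a trait of all calls confined to abemaciclib libraries. As a hypothesis, abemaciclib may bring BRG1 to distal sites, which needs more libraries and counts to test.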

How the results depend on the processing

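The windows with IgG peaks, gene-body assignment and the direct list comparison were chosen after the data were seen. The motif alternatives were not run, for want of a sequence. Only-abemaciclib regions numbered 794 at −log10 q of at least 5 and 296 above the median of both lists, where only-DMSO regions numbered 218; both classes stayed within 1.5 times under the overlap rules, equal lengths, all contigs and IgG removal. Leaving out 1 library gave 2062 to 5777 only-abemaciclib and 2979 to 5475 only-DMSO regions, since fewer libraries then had to agree. The ratio of treatment to crossed splits was 3.60 at −log10 q of at least 5 and 3.18 at equal lengths. The difference in peaks per library turned to −2698.5 at −log10 q of at least 5 and ran from −1151 to 2578 with a library left out; the cause was not tested. The excess of shared regions within treatments rose to 0.0865 at the stricter threshold. The only-DMSO gene-end odds ratio was 1.26 at that threshold and 1.34 to 1.63 without an abemaciclib library; the cause was not tested. The only-abemaciclib ratio against crossed pairs stayed under 1 and past the threshold in every alternative run, from 0.208 at the stricter threshold to 0.479 with summits within 250 bp. The direct list comparison passed 1 list where the planned tests passed 0; it passed 0 lists within 1 kb of a gene end and at equal lengths, and 2 with assignment by gene body. Of 66 named regions, 38 kept their calls at the stricter threshold and 57 at equal lengths.

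Nothing in the labels says whether same-numbered libraries were prepared together. Their call differences correlated at 0.0113 over regions, which cannot show that they shared no culture or batch. Taken as a replicate block, the pairs gave means of 7003.5 only-abemaciclib and 6556.5 only-DMSO regions, as 1 library per arm sufficed, and a gene-end odds ratio of 0.534 between them.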

Other observations

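The direct comparison for luminal genes, the clusters by gene and the comparison of chromosome 20 with and without windows that hold an IgG peak were chosen after the data were seen.

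BMP7, which encodes a bone morphogenetic protein, had the most only-abemaciclib regions of any gene, 10 in 87.7 kb of chromosome 20 (57157094 to 57244816), with 0 only-DMSO regions, 1 crossed pair and 9 regions called in 1 library. The gene had 5 regions called in all 4 libraries, outside that stretch. The libraries called 1 and 0 regions in the stretch with DMSO and 17 and 13 with abemaciclib, and the median percentile ranks of the 10 regions were 27.2 and 31.0 in the abemaciclib lists. In all, 10 genes had at least 3 only-abemaciclib regions and 6 at least 3 only-DMSO regions. The former included SULF2, RIPOR3 and ZMYND8 on chromosome 20 and TBX4 on chromosome 17, of which ZMYND8 also had 1 only-DMSO region and 12 called in all 4 libraries. The latter were led by ACSL3 with 4. In permutations the median was 2 such genes for only-abemaciclib regions (upper 95% bound 5). It was 4 for only-DMSO regions (upper 95% bound 7), so the 6 only-DMSO genes are no excess. The 10 only-abemaciclib genes exceed their bound, but neighbouring regions are not independent, so no p-value is given for these clusters. All 10 BMP7 regions lay in 1-Mb windows that hold an IgG peak, although no IgG peak fell in the cluster. DNA copy number was not measured, and a gain of BRG1 at BMP7 cannot be read from these calls.

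Chromosome 20 held 87 only-abemaciclib regions, with an odds ratio of 1.84 against crossed pairs (Fisher's exact p = 0.000158). The 87 include the 10 BMP7 regions. All p-values by chromosome count neighbouring regions as independent, so they are too small. Without windows that hold an IgG peak, 39 regions were left and the ratio was 1.11 (Fisher's exact p = 0.673). Only-DMSO regions were fewer on chromosome 20, with an odds ratio of 0.528 (Fisher's exact p = 0.00234, adjusted p = 0.0359) that was 0.539 without those windows (Fisher's exact p = 0.0101). Only-abemaciclib regions were fewer on chromosome 19, with a ratio of 0.531 (Fisher's exact p = 0.0010, adjusted p = 0.0231) and 0.529 without the windows (Fisher's exact p = 0.00115). Of the 118 IgG peaks, 35 lay on chromosome 20 and 28 on chromosome 17.

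Oestrogen response and luminal genes were set directly between the 2 treatment classes. Only-DMSO regions held 15 of 1317 and only-abemaciclib regions 1 of 1028, an odds ratio of 11.8 (Fisher's exact p = 0.00167, adjusted p = 0.0218 over 13 lists). Within deciles of rank the Mantel-Haenszel odds ratio was 10.4 (1.51 to 71.6). The lower limit barely clears the bound of 1.5 and rests on 1 only-abemaciclib region. Ranks of the 2 classes come from different lists and are not on one scale, so this cannot settle whether peak strength accounts for the ratio. The adjusted p was 0.0514 at equal list lengths, where the odds ratio was 10.3, and 1 within 1 kb of a gene end, where the ratio fell to 1.95 (5 of 435 against 1 of 169 regions). It was lowest, 0.00687, with assignment by gene body, and the planned tests against crossed pairs did not pass. YAP/TEAD targets, with 7 only-DMSO and 0 only-abemaciclib regions, had an adjusted p of 0.134 in the same comparison. With assignment by gene body they held 12 of 1560 and 0 of 1226 regions (Fisher's exact p = 0.00177, adjusted p = 0.0115), and over the other settings the adjusted p ran from 0.134 to 1. A loss of BRG1 at luminal genes cannot be read from this, since a uniform loss of signal was left open for only-DMSO regions.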
